A study of Rattus norvegicus with 6 samples.

How the data were processed

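The samples were 6 small RNA libraries from extracellular vesicles of rat BMSCs, 3 from cultures at 1% oxygen and 3 from cultures at 21% oxygen, both at 5% carbon dioxide. Per the labels' protocols, cells were grown at 37 degrees in medium with 10% fetal bovine serum, vesicle RNA was extracted, adaptors were ligated to both ends, and the reverse-transcribed and amplified libraries were selected by size and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, cutadapt 1.9.3, Novoalign 3.02.12 and the rat build rn6 were used, with no role or order stated. The counting program, the miRNA annotation release and any filter are not given in the sources used here.

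The authors deposited tag counts per mature miRNA and precursor, which per the file headers are raw, and a second table of normalized tag counts. The values of the deposited normalized table were treated as a score. They are whole numbers close to the count times 1 factor per library, but not always its rounded product. In hypoxia replicate 1, for example, a count of 239 stands beside a value of 478. The method behind the factor is not stated. The factors were 2.006, 1.900 and 1.038 for hypoxia and 2.339, 1.161 and 1.170 for normoxia. A blank cell was taken as 0. No count of 1 occurs, and the smallest listed count is 2 (7 in normoxia replicate 2), so the table may list only values above a minimum. For that reason no upper limits are given for unlisted miRNAs, and no fold is given as a measure of size against a group with no listed count.

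The table had 353 rows and 322 mature names, because a miRNA with several precursors is repeated. Rows were reduced to 311 distinct mature sequences, 197 annotated and 114 unannotated ones, which per the file headers carry a mark in their names, a choice made after the files were seen. A total of 11 names shared a sequence with another. Groups, tests, the rule for named miRNAs, the 20 miRNA lists and most alternatives were set before the data were examined. Total counts per library ran from 106954 to 248542, and 147 sequences had a count in 1 library only, which limits precision for all but the abundant miRNAs. For shares of counts in a single library, 95% exact binomial intervals were computed.

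Counts were tested with edgeR 4.0.16 in R 4.3.3. filterByExpr (minimum count 10, minimum total count 15) kept 107 sequences, 100 annotated and 7 not, and left out 204. TMM factors, estimateDisp, glmQLFit with robust estimates and glmQLFTest were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled by the TMM factors, which ran from 0.904 to 1.25. The common biological coefficient of variation was 1.07. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry from limma 3.58.1. The test on miR-106b-5p that was planned could not be made after the filter, and the number of libraries that list it is given in its place.

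The miRNAs named in the text follow a rule set in advance. They are the members of the miR-106b~25 cluster and miR-210-3p, the miRNAs called or, with fewer than 5 called in a direction, the 6 with the smallest p in that direction, the 10 most abundant, and in each list the 2 tested members with the smallest p and the most abundant one. This gave 44 miRNAs. miR-17-5p and miR-20a-5p, and those described only in the closing section, were named after their values were seen.

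The fit was tested on simulated counts for the 107 sequences in 20 simulations with 30 changed sequences each. With the fitted spread 0.519% of unchanged sequences were called. With a dispersion of 0.05 in place of the fitted one, 79.5% of 2-fold and 100% of 4-fold changes were called. In unchanged simulations the preset camera test gave a p under 0.05 for 5.91% of list tests and the estimated one for 0.455%. Only the abundant let-7 and miR-98 family, with 9 tested members, was shifted 4-fold. Its unadjusted p in the preset camera test was under 0.05 in 100% of simulations. Sequences were drawn independently, while the estimated correlation of this list was 0.43 in the real data. Scarcer or smaller lists were not shifted, so this share does not apply to them.

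The alternatives were RLE and upper-quartile factors, library totals only, no robust estimates, no filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, limma on the authors' normalized table with a pseudocount of 1 or 10, the replicate number as a block, each library left out in turn, and other thresholds. Single values were compared by exact permutation tests in scipy 1.17.1 with Python 3.11.15. Of 187 annotated precursors, 174 matched a symbol in the rat gene table (assembly GRCr8). That assembly differs from rn6, so the table was used for names and neighbours only, and no coordinates are given.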

Results

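Small RNA was sequenced from extracellular vesicles (exosomes), the membrane-bound particles that cells release, of cultured rat bone marrow mesenchymal stromal cells (BMSCs). BMSCs are adherent marrow cells that can form bone. Marrow was taken from the leg bones of male rats aged 4 weeks. Cultures were kept at 1% oxygen (hypoxia) or at 21% oxygen (normoxia), with 3 libraries in each group. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Total counts were 118683, 145961 and 248542 for hypoxia replicates 1 to 3, and 106954, 205495 and 227149 for normoxia replicates 1 to 3. The 6 libraries listed 85, 183, 166, 131, 129 and 156 distinct mature sequences in that order. In total, 311 sequences were listed, 197 of them annotated miRNAs, and 56 had a count in all 6 libraries.

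The vesicles carried a small set of miRNAs at high levels in both groups. The most abundant was miR-21-5p, a miRNA that is high in many mesenchymal cells, at 20.4 to 34.6% of the counts of a library. In hypoxia replicate 1 it took 20.4% (95% exact binomial interval 20.2 to 20.7%), and in normoxia replicate 3 it took 34.6% (34.4 to 34.8%). Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The let-7 and miR-98 family, known for its part in differentiation, made up 38.5 ± 5.1% of counts under hypoxia and 41.7 ± 6.4% under normoxia (SD, n = 3 each). Its members differ by as little as 1 base, so reads may have been divided unevenly among them, and single members are uncertain. The list of miRNAs typical of mesenchymal stromal cells held 41.1 ± 4.47% of counts under hypoxia and 40.5 ± 6.95% under normoxia (SD, n = 3 each). Most of this was miR-21-5p alone, at 26.8 ± 5.91% under hypoxia and 27.8 ± 7.12% under normoxia (SD, n = 3 each). Of its 15 tested members, 8 had a fitted value above 0 and 7 below. Together the 10 most abundant miRNAs of each library took 76.5 to 86.3% of its counts. The 4 planned measures of composition were compared by two-sided exact permutation tests, where 3 against 3 libraries cannot give a p below 0.1. The exact permutation p was 1.0 for total count, 0.9 for sequences listed, 0.8 for the share of the most abundant miRNA and 1.0 for the share of the 10 most abundant, and each adjusted value over the 12 measures computed was 1.0.

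**Figure D1:**
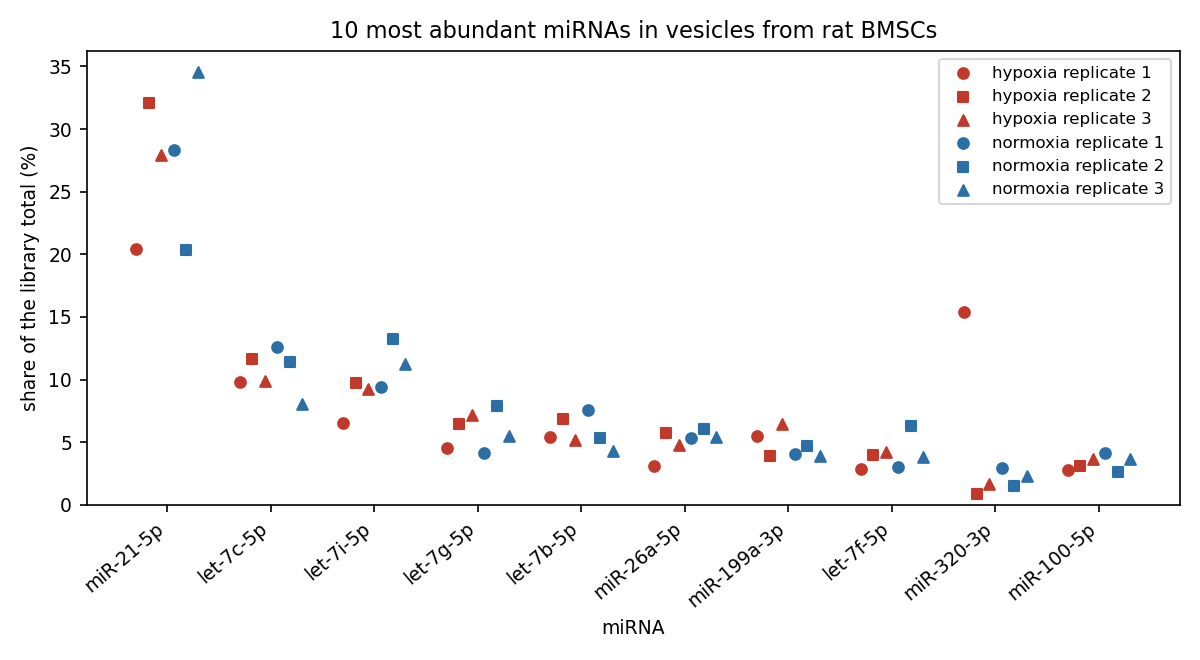
Share of the library total (%) of the 10 most abundant miRNAs in each of the 6 libraries, with hypoxia in red and normoxia in blue and one symbol for each replicate number. The miR-21-5p points lie between 20.4 and 34.6%, and the miR-320-3p point of hypoxia replicate 1 stands at 15.4%.

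The main comparison asked which vesicle miRNAs differ between cells held at 1% and at 21% oxygen. No miRNA passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, so 0 were called higher and 0 lower among 107 tested sequences. At an unadjusted p under 0.05 the same test gave 1 sequence, DESeq2 gave 1 and limma-voom gave 4, and both other tools called 0 at the adjusted threshold. The smallest adjusted p in edgeR was 0.998. Fitted values lay above 0 for 44 sequences and below 0 for 63. Their median was -0.14, and it was 0.15 over the 130 sequences tested without hypoxia replicate 1. The abundant miRNAs had the narrowest errors. For miR-21-5p the log2 fold change, hypoxia over normoxia, was -0.16 (SE 0.36), for let-7c-5p -0.14 (SE 0.31), for let-7i-5p -0.51 (SE 0.33) and for miR-199a-3p 0.19 (SE 0.30). For miR-26a-5p it was -0.39 (SE 0.35), for let-7f-5p -0.32 (SE 0.35) and for miR-100-5p -0.24 (SE 0.32). For let-7b-5p and let-7g-5p the values were -0.08 (SE 0.32) and -0.03 (SE 0.35), and both were above 0 in several other fits, such as upper-quartile factors. Without hypoxia replicate 1, miR-21-5p had 0.32, let-7c-5p 0.24, miR-26a-5p 0.14, let-7f-5p 0.15 and miR-100-5p 0.16. In that fit let-7b-5p had 0.31 and let-7g-5p 0.44, while let-7i-5p and miR-199a-3p kept their signs. The single sequence with an unadjusted p under 0.05 was the unannotated CUUGGCACCUGGUAAGCACUCA. Its unadjusted p in edgeR's model over all sequences was 0.0124, with an adjusted p of 0.998. It had 41, 28 and 29 counts in the normoxia libraries and no listed count in hypoxia.

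Precision depended on abundance. The median standard error of the log2 fold change was 1.44 over the 107 sequences and 0.415 over the 39 with a mean above 1000 CPM. In simulated data with the fitted spread of these 107 sequences, 2.5% of 2-fold changes, 16% of 4-fold changes and 36.5% of 8-fold changes were called. Among the simulated sequences above 1000 CPM those shares were 6.90%, 33.3% and 73.4%. A difference of a few fold was therefore mostly not detectable here, and the count of 0 does not show that the groups were alike.

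The series title names miR-106b-5p, which is encoded with miR-93 and miR-25 inside the gene Mcm7 in the rat gene table (assembly GRCr8). The mature miR-106b-5p (UAAAGUGCUGACAGUGCAGAU) was listed in 1 of the 6 libraries, with 21 counts in normoxia replicate 1 and none in the hypoxia libraries. The other arm, miR-106b-3p, had 43 counts in the same library alone, and miR-93-5p had 15 counts in hypoxia replicate 2 alone. All of them fell below the filter on low counts and were not tested. Without a filter, edgeR gave miR-106b-5p an adjusted p of 0.421. The only abundant member was miR-25-3p, at 10434 ± 1343 CPM under hypoxia and 16459.6 ± 3860.1 CPM under normoxia (SD, n = 3 each). Its log2 fold change was -0.66 (SE 0.34), with a 95% interval of -1.39 to 0.08 and an adjusted p of 0.998 in edgeR. Its 3 hypoxia values lay below its 3 normoxia values with TMM or upper-quartile factors, and the groups overlapped with RLE factors, library totals only or the authors' normalized table. With TMM factors, non-overlapping groups were found for 8 of 107 sequences (7.48%), where chance gives 10%. All 8 were lower under hypoxia, and 6 of them had no listed count in hypoxia replicate 1. With library totals only, 5 were lower and 3 higher. The other sequences of the AAAGUGC seed family were scarce too. miR-17-5p had 0, 4 and 8 counts under hypoxia and 0, 10 and 9 under normoxia, and miR-20a-5p had 0, 14 and 80 against 6, 0 and 0.

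**Figure D2:**
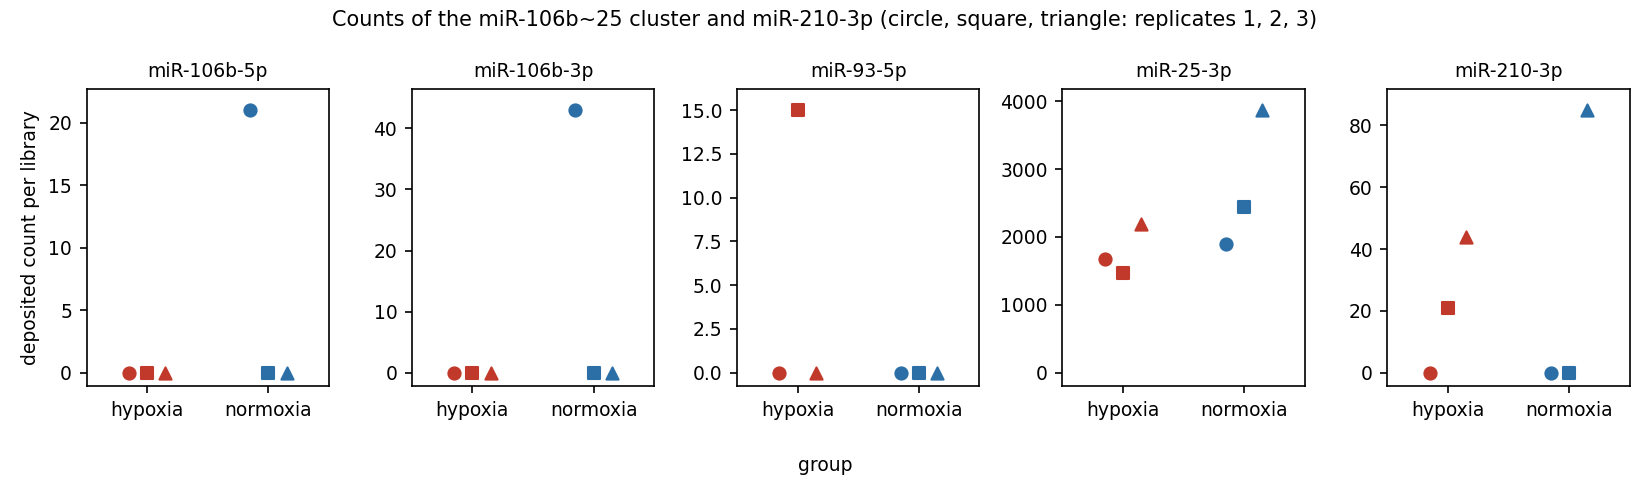
Deposited counts per library of miR-106b-5p, miR-106b-3p, miR-93-5p, miR-25-3p and miR-210-3p, with hypoxia in red and normoxia in blue, one point per library and a separate linear axis per miRNA. A count of 0 stands for a library that does not list the miRNA, and miR-106b-5p has 21 counts in normoxia replicate 1 only.

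The canonical low-oxygen miRNA, miR-210-3p, is a direct target of hypoxia-inducible factor in many cell types. It had 0, 21 and 44 counts under hypoxia and 0, 0 and 85 under normoxia. Its log2 fold change was -0.32 (SE 2.34), with a 95% interval of -5.36 to 4.73, so its counts do not check the oxygen labels in either direction. The sign was positive in the fit of limma-voom (1.48) and in both fits of the authors' normalized table (1.42 and 0.45). It was also positive with the replicate number as a block (1.88) and without hypoxia replicate 1 (0.45). Normoxia replicate 3 holds all normoxia counts of miR-210-3p, and without it no fold can be given. The fixed list of hypoxia-induced miRNAs had 12 tested members, 3 with a value above 0 and 9 below, and 0 passed the test in edgeR, also adjusted over the list alone. Its most abundant members were miR-21-5p and miR-26a-5p, given above, and miR-24-3p had -0.59 (SE 0.40). Among the miRNAs known to target HIF1A, only miR-199a-5p was tested, with -0.05 (SE 0.70). It was above 0 in 6 alternatives, among them upper-quartile factors and library totals only. The largest values were 0.61 without hypoxia replicate 1 and 0.36 without normoxia replicate 3.

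No list linked to bone formation passed the set test. The osteogenesis-promoting list had 6 tested members, 1 above 0 and 5 below, and a median of -0.34. Without hypoxia replicate 1 its median was 0.32, with miR-21-5p at 0.32, miR-26a-5p at 0.14 and miR-29a-3p at 0.45. The medians of the hypoxia-induced, Runx2-targeting, angiogenic, let-7, blood cell and serum-borne lists also changed from below 0 to above 0 without that library. So did the median of all tested sequences, from -0.14 over 107 sequences to 0.15 over 130, so this change was not particular to these lists. With all libraries, miR-22-3p had a log2 fold change of 0.78 (SE 0.55), and 0.13 without hypoxia replicate 1. For miR-29a-3p, a regulator of collagen genes, it was -0.36 (SE 1.34), and for miR-218a-5p -0.44 (SE 0.68). The Runx2-targeting list, named for a transcription factor of osteoblasts, had 3 members above 0 and 3 below, among them miR-30d-5p at 0.23 (SE 0.55) and miR-30a-5p at 0.12 (SE 0.65). The angiogenic list had 2 above and 3 below, with miR-221-3p at -0.49 (SE 0.60) and miR-31a-5p at 0.61 (SE 1.48). The let-7 family had 2 of 9 members above 0, with miR-98-5p at -2.90 (SE 1.97). The 46 hypoxia counts of miR-98-5p were all in hypoxia replicate 2, and without that library its adjusted p in edgeR was 0.0723, against a group with no listed count. Of the imprinted Dlk1-Dio3 cluster, 6 members were tested, 1 above 0 and 5 below, and miR-493-5p had -1.56 (SE 1.86). The miR-30 family had 3 of 4 tested members above 0. In the mesenchymal list miR-99b-5p had -0.36 (SE 0.36). Of the miR-15/16 family only miR-16-5p was tested, with -1.82 (SE 1.75), of the miR-29 family only miR-29a-3p, and of the miR-17~92 cluster and its paralog none of the 4 listed members. In edgeR's camera test with a preset correlation of 0.01, 0 of 11 lists with at least 3 tested members passed, and every adjusted p was 0.941. With an estimated correlation 0 passed, at an adjusted p of 0.956 for each list, and fry, which asks whether members move one way on balance, gave adjusted p-values from 0.810 to 0.932. For the osteogenesis-promoting, angiogenic and serum-borne lists the median was below 0 while the direction of camera was upward. Adjusted over the list alone, 0 members of any of the 20 lists passed.

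**Figure D3:**
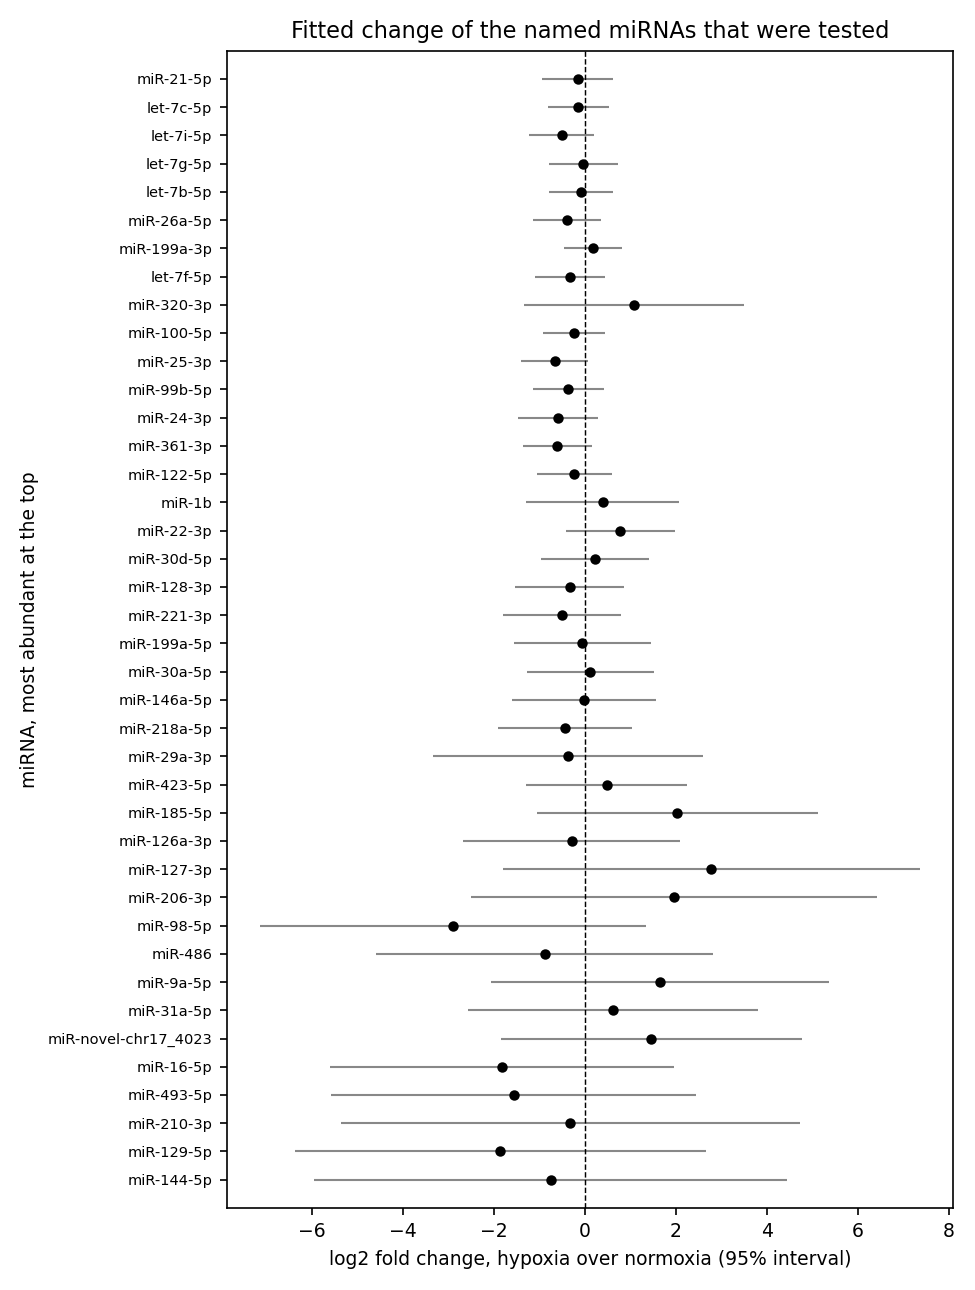
Log2 fold change of hypoxia over normoxia from edgeR for 40 named miRNAs listed in both groups, ordered by mean CPM, with points for the fitted value and lines for the 95% interval (n = 3 libraries per group). All 40 intervals include 0, and they mostly widen toward the scarce miRNAs at the bottom.

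One library stood apart from the rest, hypoxia replicate 1. It listed 85 sequences, and miR-320-3p took 15.4% of its counts against at most 2.92% in any other library. Its mean correlation with the other libraries was 0.755, against 0.807 to 0.855 for the others. Several miRNAs with the smallest unadjusted p-values on the higher side took their values largely from it. miR-320-3p had a log2 fold change of 1.09 (SE 0.99) with all libraries and -0.64 without this library. For miR-127-3p the values were 2.78 (SE 2.13) and -1.42, and for miR-9a-5p, a neural miRNA, 1.66 (SE 1.72) and -1.24. Other values stayed above 0 but were smaller without it. For miR-185-5p they were 2.04 (SE 1.43) and 0.88, and for the unannotated CUCACCUGGAGCAUGUUUUCU 1.46 (SE 1.54) and 0.55. Without it edgeR called 0 of 130 sequences, with 5 at an unadjusted p under 0.05. On the lower side, miR-361-3p had -0.60 (SE 0.35). Its 3 hypoxia values lay below its 3 normoxia values with TMM, RLE or upper-quartile factors, and overlapped with them with library totals only or in the authors' normalized table.

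Each list of markers of other sources held at most 1.89% of the counts of a library. Such a list holds only marker miRNAs, so its share does not measure all counts from that source. Not all single members were scarce, with means over all libraries of 6184 CPM for miR-122-5p and 4978 CPM for miR-1b. The striated muscle list made up 1.89% of the counts of hypoxia replicate 1 and 0.147 to 0.506% of the others, mostly miR-1b, with a log2 fold change of 0.39 (SE 0.76) and -1.09 without hypoxia replicate 1. miR-206-3p, also a muscle miRNA, had 1.96 (SE 2.07) and 0.36 without that library. Its 61 normoxia counts were all in normoxia replicate 1, and without that library its adjusted p in edgeR was 0.0635, against a group with no listed count. The serum-borne list held 0.748 ± 0.193% of counts under hypoxia and 0.762 ± 0.316% under normoxia (SD, n = 3 each). It was led by the liver miRNA miR-122-5p, at 5683 ± 587 CPM under hypoxia and 6684 ± 2384 CPM under normoxia (SD, n = 3 each), with a log2 fold change of -0.23 (SE 0.38). miR-423-5p had 0.48 (SE 0.82). The culture medium contained 10% fetal bovine serum. How much of the counts came from the serum was not tested. The blood cell list held 0.149 ± 0.0775% of counts under hypoxia and 0.177 ± 0.0125% under normoxia (SD, n = 3 each), the endothelial list 0.0581 ± 0.0277% of counts under hypoxia and 0.064 ± 0.0286% under normoxia (SD, n = 3 each) and the epithelial list 0.00137 ± 0.00237% of counts under hypoxia and 0.008 ± 0.00697% under normoxia (SD, n = 3 each). The neural list had 3 tested members, miR-9a-5p, miR-129-5p at -1.85 (SE 2.10) and miR-128-3p at -0.33 (SE 0.56). None of the tested members of the muscle, serum, blood cell, endothelial and neural lists is also in the mesenchymal list, and both the serum and the blood cell list hold miR-486. In these lists miR-486 had a log2 fold change of -0.87 (SE 1.72), miR-144-5p -0.75 (SE 2.41), miR-146a-5p -0.02 (SE 0.73) and miR-126a-3p -0.29 (SE 1.10). In two-sided exact permutation tests added after the data were seen, the shares of the serum, blood cell, endothelial, epithelial and muscle lists gave p = 1.0, 0.9, 0.8, 0.4 and 1.0, with adjusted values of 1.0.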

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

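At an adjusted p under 0.05 the count of 0 called miRNAs held in both directions under every other fit that was run, and at an adjusted p under 0.1 in the main one. So did 0 called lists, although the 11 lists were not recomputed in DESeq2, which gave an adjusted p for 105 of 107 sequences. In edgeR 1 sequence had an unadjusted p under 0.05, in DESeq2 1 and in limma-voom 4, and the smallest adjusted p over the alternatives was 0.0635, for miR-206-3p without normoxia replicate 1. It was 0.0723 for miR-98-5p without hypoxia replicate 2. In each case the library left out was the only one of its group that listed the miRNA, so these fits compare with a group that has no listed count. The smallest without a filter was 0.120. At the looser threshold of an unadjusted p under 0.05 with a fold of at least 1.5, the count did not hold, with 1 miRNA lower and 0 higher. The alternatives with annotated miRNAs only and with one entry per name were chosen after seeing the data, and the latter changed no tested sequence. miR-106b-5p has no fold change because the filter removed it. The number of normoxia minus hypoxia libraries that list it was 1 with all libraries and 0 to 1 with each left out. The median fitted value of all tested sequences was -0.14 with TMM factors, -0.02 with upper-quartile factors and -0.03 with library totals, so signs near 0 depend on the scaling. They also depend on the libraries and sequences used. The median was 0.15 without hypoxia replicate 1, 0.096 with a mean count of at least 50, 0.074 without a filter and 0.0080 with annotated miRNAs only. In all other fits it was below 0.

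Of 41 tested named miRNAs, 20 kept their sign under every alternative that gave a value and 21 did not, and 10 of 11 list medians changed sign at least once. The number of sequences with non-overlapping groups was 7 to 8 over the scalings, but not the same sequences. None of these fold changes or medians passed the test before or after the change of sign. With RLE factors the value was 0.0037 for miR-146a-5p. With upper-quartile factors the values were 0.051 for let-7g-5p, 0.0026 for let-7b-5p, 0.085 for miR-199a-5p and 0.082 for miR-146a-5p. With library totals only the values were 0.060 for let-7g-5p, 0.031 for let-7b-5p, 0.014 for miR-199a-5p, 0.047 for miR-146a-5p and 0.0013 for the median of the Runx2-targeting list. Without a filter the values were 0.0088 for miR-146a-5p, 0.14 for the median of the Runx2-targeting list and 0.18 for the median of the angiogenic list. With a mean count of at least 50 the values were 0.0010 for miR-21-5p, 0.0097 for let-7c-5p, 0.13 for let-7g-5p, 0.070 for let-7b-5p, 0.12 for miR-199a-5p, 0.13 for miR-146a-5p, 0.037 for the median of the Runx2-targeting list, 0.0097 for the median of the let-7 and miR-98 family list and 0.78 for the median of the neural list. In DESeq2 the value was 0.0020 for miR-146a-5p. In limma-voom the values were 1.48 for miR-210-3p, -0.37 for miR-1b and -0.014 for the median of the mesenchymal stromal list. In the authors' normalized table with a pseudocount of 1 the values were 1.42 for miR-210-3p, 0.021 for let-7c-5p, 0.12 for let-7g-5p, 0.089 for let-7b-5p, 0.15 for miR-146a-5p, -0.15 for miR-1b and 0.021 for the median of the let-7 and miR-98 family list. With a pseudocount of 10 the values were 0.45 for miR-210-3p, 0.021 for let-7c-5p, 0.12 for let-7g-5p, 0.089 for let-7b-5p, 0.14 for miR-146a-5p, -0.14 for miR-1b and 0.021 for the median of the let-7 and miR-98 family list. With annotated miRNAs only the values were 0.013 for let-7c-5p, 0.11 for let-7g-5p, 0.073 for let-7b-5p, 0.062 for miR-199a-5p, 0.12 for miR-146a-5p, 0.037 for the median of the Runx2-targeting list and 0.013 for the median of the let-7 and miR-98 family list. The ranges with each library left out in turn were -0.90 to 7.26 for miR-210-3p, -1.42 to 3.54 for miR-127-3p, -0.64 to 1.67 for miR-320-3p, -1.24 to 2.66 for miR-9a-5p, -0.31 to 0.32 for miR-21-5p, -0.20 to 0.24 for let-7c-5p, -0.17 to 0.44 for let-7g-5p and -0.20 to 0.31 for let-7b-5p. For other results they were -0.56 to 0.14 for miR-26a-5p, -0.46 to 0.15 for let-7f-5p, -0.37 to 0.16 for miR-100-5p, -0.24 to 0.61 for miR-199a-5p, -0.64 to 0.45 for miR-29a-3p, -0.36 to 0.57 for miR-146a-5p, -1.09 to 0.98 for miR-1b and -0.41 to 0.23 for the median of the hypoxia-induced list. Ranges also crossed 0 at -0.40 to 0.32 for the median of the osteogenesis-promoting list, -0.19 to 0.33 for the median of the Runx2-targeting list, -0.30 to 0.32 for the median of the angiogenic list, -0.20 to 0.31 for the median of the let-7 and miR-98 family list, -0.99 to 0.22 for the median of the blood cell list, -0.55 to 0.075 for the median of the serum-borne list, -0.52 to 0.16 for miR-126a-3p and -0.040 to 0.85 for miR-30d-5p. The last were -0.51 to 0.12 for miR-128-3p, -0.068 to 0.32 for the median of the mesenchymal stromal list, -0.88 to 0.18 for the median of the Dlk1-Dio3 cluster list, -1.03 to 0.12 for the median of the neural list, -0.30 to 0.19 for miR-122-5p, -0.69 to 0.046 for miR-221-3p and -0.041 to 0.84 for miR-30a-5p. The 7.26 for miR-210-3p comes from the fit without normoxia replicate 3, the only normoxia library that lists it. It depends on how the model treats a group without counts and measures no fold. Leaving out hypoxia replicate 1 turned 22 signs, and that library stands apart in composition. Beyond the libraries left out, the cause was not tested. The median standard error was 1.44. In simulations at the same counts, 16% of 4-fold changes were called with the fitted spread and 100% with a dispersion of 0.05, so the spread between libraries bears on this error and depth alone does not set it.

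The replicate numbers were also fitted as a replicate block. Deviations of libraries with the same number correlated at 0.23, 0.03 and 0.12, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. The block gave 0 called miRNAs, 2 at an unadjusted p under 0.05, and values of 1.88 for miR-210-3p, -0.011 for miR-30d-5p and -0.46 for miR-1b.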

Other observations

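Apart from the comparison with other splits of the libraries, the tests in this part were chosen after the results they measure had been seen. For all of them, what each outcome would mean was written down, cutoffs included, with those results in view, so none can uphold an explanation.

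Several miRNAs outside the named set were high in hypoxia replicate 1. miR-143-3p, a miRNA of smooth muscle and other mesenchymal cells, reached 10937 CPM of its library total, 1.72 times the highest other library. miR-140-3p, known from cartilage, was at 1222 CPM (3.45 times) and miR-30e-5p at 986 CPM (18.0 times). These CPM are not scaled by the TMM factors. Hypoxia replicate 1 had the largest factor, 1.25, so the ratios would be smaller on the scaled CPM. The unannotated sequence UCAGACUUCUGCUCACCCACGA had 203, 6 and 68 counts under hypoxia and none listed under normoxia. Being listed in all libraries of 1 group and none of the other occurred for 2 sequences, and for up to 5 in other splits of the 6 libraries.

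The count of 0 called miRNAs was compared with the other splits of the 6 libraries into 3 and 3. All 10 splits called 0 miRNAs, with a highest other value of 0, and all 10 called 0 lists, with a highest other value of 0. For non-overlapping groups the real split gave 8 sequences, 7 of the 10 splits gave as many, and the highest other split gave 21. These counts are on TMM-scaled CPM. With library totals only the real split also gave 8, 5 lower and 3 higher, and the highest other split gave 22. With 10 splits no share under 0.05 can be reached.

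Hypoxia replicate 1 listed 85 sequences. A lower depth is argued against, because after thinning every library to 106954 counts it listed at most 85 sequences over 100 draws, while no other library listed fewer than 126. A higher listing minimum in that library is argued against too, since it listed 6 sequences at 20 or fewer counts, the lowest at 2, while it lacked 22 of 78 sequences expected at over 20 counts. Few starting RNA molecules, copied many times, may account for it. The other libraries lacked 2, 3, 2, 11 and 2 such sequences. Over the 6 libraries, missing sequences related to the percent listed at 10 or fewer counts with Spearman's rho -0.941 and Pearson's r -0.452, both with an exact permutation p of 0.0167, the smallest these values can give. Without the 2 libraries farthest on the second measure r was -0.794 over 4 libraries, too few to test, so this stays open, as does a biological difference of that culture.

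Part of the sequences without an annotated name may be fragments of transfer RNA. A motif of the D arm of transfer RNAs occurred in 7 of 114 such sequences and 2 of 197 annotated ones (Fisher's exact test, two-sided, p = 0.0136). The motif was chosen after the sequences had been seen, so this stays a hypothesis. Of the 7, the sequence listed only in normoxia replicate 2 with 15 counts shares most of its bases with the annotated miR-24-3p. For that sequence the motif is no sign of transfer RNA, and no test without it was run. The motif marks only 1 part of a transfer RNA, so the 7 are no upper limit. The bases CCA, which end mature transfer RNAs, ended 3 of the 114, none of them with the motif, and 2 of the annotated ones. Other parts were not searched. Of the 114, 49 were 19 bases or shorter, against 0 of the annotated ones, and 94 had a count in 1 library only.

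Differences shared by miRNAs with a common seed might be diluted over paralogs. Counts summed over 261 seeds gave 86 tested families, 0 called in edgeR and 1 at an unadjusted p under 0.05, with a smallest adjusted p of 0.996; other tools were not run on the families. The median standard error was 1.37, so for many families this does not exclude shared differences of a few fold. Some abundant families had smaller errors. The log2 fold change was -0.10 (SE 0.41) for the let-7 seed GAGGUAG and -0.58 (SE 0.38) for AUUGCAC, the seed of miR-25-3p. For AAAGCUG, the seed of miR-320-3p, it was 1.01 (SE 0.73). The AAAGUGC family, which holds miR-106b-5p, had summed counts of 0, 33 and 88 under hypoxia and 27, 10 and 9 under normoxia. Its log2 fold change was 1.02 (SE 1.97), with an adjusted p of 0.996 in edgeR.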
